A study of Mus musculus with 16 samples.

How the data were processed

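The deposited files, 1 for each of 16 libraries, hold per the file headers the estimated counts of each transcript, its TPM, and its length and effective length in bases. The authors' estimated counts were used as the main measure. The deposited TPM and the effective length, an other unit per the file headers, served only for an alternative with length-scaled counts. Per the submitters' processing notes, the upstream tools were fastp 0.20.0 and kallisto 0.46.1 with the mouse build GRCm39. Per the labels, libraries were stranded, poly(A)-selected and sequenced from a single end, RNA of sorted cells was prepared with another kit than RNA of unsorted cells, and the samples with the same name are biological replicates.

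Transcript counts were summed per gene and rounded. Of 121798 transcripts in the files, 120739 matched the GENCODE M21 annotation and 1059 did not and were left out. That annotation is on GRCm38, another build than that of the files, so it was used for gene names, gene types and gene order alone, and no coordinates are given. The files gave 35613 genes. Replicates were checked for duplicated data, and no pair of libraries was closer than counting error allows (chi-square per degree of freedom 10.6 to 64.1).

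The comparisons, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, and the genes and tests chosen later are named as such. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in a single fit of the 15 replicated libraries with a term for each of 5 groups. The fit used TMM normalization and the edgeR filter on low counts (minimum count 10, minimum total 15), which left 15533 genes. The common dispersion was 0.047 and 10 residual degrees of freedom remained. Adjusted p values are Benjamini-Hochberg values from edgeR over all tested genes, and the threshold was 0.05. The standard error of a log2 fold change was derived from the F statistic. The CPM shown were scaled with TMM factors over all 16 libraries. TMM factors were 0.767 to 0.867 in bulk MPC and 1.09 to 1.15 in the sorted libraries. The 10 most abundant genes held 12% to 14.1% of counts in bulk MPC and 6.25% to 7.72% in sorted cells and bulk myoblasts.

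In all, 7 comparisons were fitted: GFP+ MPC with GFP+ myoblasts, bulk MPC with bulk myoblasts, differentiated with bulk myoblasts, bulk MPC with differentiated myoblasts, GFP+ MPC with bulk MPC, GFP+ myoblasts with bulk myoblasts, and the difference between the sort effects of the MPC and myoblast cultures. The high-passage library has no replicate and was left out of the fit; it was described by its CPM and by its distance to group means on the log scale with a prior count of 2.

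A total of 25 gene lists were tested in each comparison with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Camera tests a list against the other genes, whereas fry tests it against no change. The lists were muscle stem cell markers, myogenic regulatory factors, sarcomere and contraction, myoblast fusion and neuromuscular synapse, Notch pathway, embryonic and fetal muscle progenitor genes, Wnt beta-catenin targets, TGF-beta targets, cAMP and CREB targets, cell cycle, senescence and p53 targets, and glycolysis. The others were oxidative phosphorylation, cholesterol biosynthesis, basement membrane and collagen genes, interferon-stimulated genes, pluripotency genes, sorting and dissociation stress genes, and markers of fibroblasts and fibro-adipogenic progenitors, endothelium, macrophages and leukocytes, Schwann cells, pericytes and smooth muscle, tenocytes, and adipocytes. Members were chosen from general knowledge of the genes, and a gene can be on several lists, so the lists are not independent. A count adjusted over the list alone used the p values of its members only. The level of a list in a library is the median over its tested members of the log2 CPM minus the mean of the other 2 libraries of the group. It was computed after the results were seen.

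Genes were named by a fixed rule. It allowed 10 genes in any comparison (Pax7, Myf5, Myod1, Myog, Myh3, Ckm, Axin2, Mki67, Cdkn1a and 1 that is not reported here). For each list it allowed up to 4 members with the largest changes past the threshold, up to 2 against the majority, and those not past the threshold where these were 5 or fewer. It also allowed the 5 protein-coding genes with the largest rise and the 5 with the largest fall at a mean of at least 10 CPM in the higher group, predicted gene names left out. List examples and top genes had to change the same way in all 3 pairs of libraries with the same number. Any other gene named was chosen after its values were seen.

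Where a group had 0 counts of a gene, the fold is a lower bound from 3 counts over the group, the upper 95% limit of a count of 0. Where it had 1 to 3 counts, the ratio has a 95% counting interval. Leaving out a library of such a group changes the reads behind these values, so they then move by construction. Both cover counting error only, not differences between cultures, and the fitted log2 value is not given for such genes, except for the difference of sort effects, for which no bound was computed.

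The fit was tested on simulated data, with 50 genes changed by each of several folds. In the design of GFP+ MPC against GFP+ myoblasts, with 15168 genes, edgeR recovered 24% of 1.5-fold, 70% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, and 7 unchanged genes passed (4.6% of calls). For the difference of sort effects, it recovered 4%, 40%, 80% and 100%, and 9 unchanged genes passed (7.4% of calls). In bulk MPC against bulk myoblasts, 10 did (6.6% of calls). With the data of the design named at the start, 36 unchanged genes passed with DESeq2 1.42.0 (18.5% of calls) and 13 with voom (8.4%). In these simulations 1.5-fold changes were mostly missed. Far fewer genes changed in them than passed in the real comparisons, so these rates need not hold for the real data. Each group had 3 replicates and each library 19.3 to 29.1 M counts.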

Results

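RNA was sequenced from 16 libraries of cultured mouse muscle cells that carry a nuclear GFP reporter of Pax7, the transcription factor that marks muscle stem cells. Of these, 15 formed 5 groups of 3 replicates. The groups were unsorted (bulk) myoblasts at passage 3, myoblasts sorted for GFP (GFP+ myoblasts) at passage 5 to 6, myoblasts after 3 days in differentiation medium, and cultures that the labels call MPC, taken unsorted (bulk MPC) or after sorting for GFP (GFP+ MPC). The labels do not spell out MPC. The MPC cultures grew for 5 to 6 passages in a medium with 5 µM forskolin, an activator of adenylyl cyclase, 5 µM RepSox, an inhibitor of the TGF-beta type I receptor, and 3 µM of a compound the labels name CHIR9901. Another GFP+ MPC library came from high-passage cells and had no replicate.

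Total estimated counts (M, mega) were 29.1, 19.9 and 26.9 M in bulk myoblast replicates 1 to 3, 28.4, 23.1 and 19.3 M in GFP+ myoblasts, and 23.3, 20.1 and 19.6 M in differentiated myoblasts. They were 28.2, 24.3 and 20.2 M in bulk MPC, 19.6, 21.1 and 22.6 M in GFP+ MPC, and 21.4 M in the high-passage library. Values are log2 fold changes ± standard error, or counts per M (CPM) as mean ± SD, with n = 3 in each group. All comparisons tested 15533 genes with edgeR, and a gene or list passed at an adjusted p under 0.05. Where a list has only a single pair of counts, the pair adjusted over the list alone was equal to it. The main axis of variation held 50.7% of the variance and set the sorted libraries, at -79.9 to -122, apart from differentiated myoblasts and bulk MPC, at 71.6 to 126. MPC libraries lay at 61.8 to 110 on the next axis (28% of the variance), and all other groups lay below 0. The level of a library over a list is the median of log2 values against the mean of its group's other 2 replicates. Bulk MPC replicate 2 stood apart from replicates 1 and 3. Its level was 1.11 over the cell cycle list, 1.80 over basement membrane and collagen genes, 0.76 over Notch genes and 2.52 over fibroblast and fibro-adipogenic progenitor markers.

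Sorted cells of the MPC culture and sorted myoblasts had Pax7 levels that did not differ past the threshold, at 766 ± 148 and 902 ± 92.2 CPM (-0.23 ± 0.33, adjusted p = 0.577). This comparison addressed how Pax7-expressing cells of the small-molecule medium differ from Pax7-expressing cells of ordinary myoblast culture. Myod1, the factor of committed myoblasts, fell by 2.23 ± 0.28 in GFP+ MPC, to 195 ± 95.2 from 918 ± 35.3 CPM. The Wnt feedback gene Axin2 rose by 4.72 ± 0.38. The cell cycle inhibitor Cdkn1a changed by -1.14 ± 0.23. Myf5 rose by 0.91 ± 0.26 (adjusted p = 0.0118) and the proliferation marker Mki67 by 1.34 ± 0.38 (adjusted p = 0.0108); without GFP+ myoblast replicate 2, these adjusted p values were 0.0529 and 0.0509. Myogenin (Myog), which drives terminal differentiation, did not pass at 0.14 ± 0.42, adjusted p = 0.807.

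The list of muscle stem cell markers was on balance higher in GFP+ MPC, with 14 of 28 tested members higher and 6 lower (14 and 7 adjusted over the list alone) and a median of 0.87 (adjusted p = 0.0378, adjusted p = 0.489 with an estimated correlation). Its largest rises were in the calcitonin receptor gene Calcr, at least 58.4-fold higher against GFP+ myoblasts at 0 counts, the cell cycle inhibitor Cdkn1c (8.64 ± 0.77), and the Notch effectors Heyl (5.36 ± 0.72) and Hey1 (4.83 ± 0.31). Cd34 (-3.53 ± 0.60) and Vcam1 (-2.26 ± 0.50) fell. The list did not pass without GFP+ myoblast replicate 3 (adjusted p = 0.112) or GFP+ MPC replicate 3 (adjusted p = 0.076). Genes of the Notch pathway had 9 of 15 tested members higher and 2 lower, with a median of 1.33 (adjusted p = 0.0144, adjusted p = 0.489 with an estimated correlation). Hey1, Heyl and Notch3 are on this list and on that of stem cell markers, so the lists are not independent. Nrarp, a Notch-induced feedback inhibitor, changed by 4.69 ± 0.48 and Dtx4 by 3.98 ± 0.41, whereas the ligand gene Jag2 changed by -1.59 ± 0.19. Among the myogenic regulatory factors, 3 of 7 tested members higher and 1 lower did not move the list (median 0.14, adjusted p = 0.81), and Myf6 (2.45 ± 0.50) and Mef2c (1.75 ± 0.28) rose while Myod1 fell. Bulk MPC held Myf6 and Mef2c at means of 204 and 1220 CPM. Whether RNA carried over from bulk MPC or differentiating cells raised them was not tested. Without GFP+ myoblast replicate 1, Heyl was at 6.19 and Nrarp at 5.49, and without GFP+ MPC replicate 2 Cd34 was at -4.46.

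Sarcomere and contraction genes were higher in GFP+ MPC than in GFP+ myoblasts, with 26 of 34 tested members higher and 1 lower and a median of 1.72 (adjusted p = 0.000199, adjusted p = 0.717 with an estimated correlation). Levels were low in both sorted groups against the unsorted cultures: embryonic myosin Myh3 was at 281 ± 135 and 77.2 ± 13 CPM (1.86 ± 0.29), perinatal myosin Myh8 at 162 ± 68.5 and 6.29 ± 3.17 CPM, and creatine kinase Ckm at 12.3 ± 8.77 and 0.522 ± 0.104 CPM (4.53 ± 0.63). For 11 of the 26 higher members, the level was within what a small carried-over share of bulk MPC RNA would give in at least 1 library. GFP+ MPC replicate 2 had a level of 1.05 over this list, with 27 of 34 members above both, and without it Ckm was at 3.82. Fusion and neuromuscular synapse genes had 0 of 12 tested members higher and 7 lower (0 and 8 adjusted over the list alone), with a median of -1.33 (adjusted p = 0.00345, adjusted p = 0.489 with an estimated correlation). The acetylcholine receptor subunit genes Chrna1 (-4.14 ± 0.26), Chrnb1 (-1.91 ± 0.13) and Chrng (-1.83 ± 0.25) fell, as did Dok7 (-1.75 ± 0.22), which is needed at the synapse. GFP+ MPC replicate 1 had a level of -0.59 over this list, with 10 of 12 members below both others, and GFP+ myoblast replicate 3 a level of -0.32, with 9 below both.

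Targets of TGF-beta had 2 of 21 tested members higher and 11 lower, with a median of -0.52 (adjusted p = 0.00396, adjusted p = 0.489 with an estimated correlation). Ccn2 (-5.34 ± 0.56) and Ltbp2 (-4.13 ± 0.60) fell, against a rise of Postn (6.06 ± 1.26). Wnt beta-catenin targets were included on the reading that the last compound is the GSK3 inhibitor of nearly the same name, and 5 of 16 tested members higher and 5 lower gave a median of 0.15 (adjusted p = 0.81). Axin2 and the receptor genes Tnfrsf19 (4.80 ± 0.35) and Lgr5 (4.50 ± 0.39) rose, while Lgr6 changed by -7.51 ± 1.04. Targets of cAMP and CREB had 9 of 20 tested members higher and 6 lower (median 0.23, adjusted p = 0.804). Of these, Rgs2 (4.10 ± 0.35) and the phosphodiesterase gene Pde3a, 1870-fold (95% counting interval 336 to 74000) higher, rose, whereas Nr4a2 (-4.31 ± 0.41) and Ppargc1a (-4.81 ± 0.55) fell. Without GFP+ MPC replicate 2, Postn was at 4.68 and Ppargc1a at -5.53. Without GFP+ myoblast replicate 1, which held its only count there, Pde3a was at least 372-fold higher. GFP+ myoblast replicate 3 had a level of -0.52 over the TGF-beta list, with 16 of 21 members below both.

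Cell cycle genes had 11 of 28 tested members higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.46 (adjusted p = 0.0126, adjusted p = 0.872 with an estimated correlation). Cyclin E1 (Ccne1) changed by 1.77 ± 0.18 and the mitotic kinase gene Aurkb by 1.41 ± 0.37, while Rrm2, a subunit of ribonucleotide reductase, changed by -1.32 ± 0.31. The list did not pass without GFP+ myoblast replicate 2 (adjusted p = 0.0593) or GFP+ MPC replicate 3 (adjusted p = 0.076). GFP+ myoblast replicate 3 had a level of 0.63, and replicate 2 a level of -0.44. In the list of senescence genes and p53 targets, 2 of 17 tested members higher and 11 lower (2 and 12 adjusted over the list alone) gave a median of -1.0 (adjusted p = 0.00396, adjusted p = 0.696 with an estimated correlation). Plk2 (-2.65 ± 0.17), the p53 regulator Mdm2 (-2.25 ± 0.21) and Ccng1 (-1.98 ± 0.28) fell and the lamin gene Lmnb1 (1.04 ± 0.22) rose. Over this list, GFP+ MPC replicate 1 had a level of 0.76, with 13 of 17 members above both, and replicate 2 a level of -0.87, with 14 below both.

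Oxidative phosphorylation genes had 15 of 25 tested members higher and 0 lower, with a median of 0.31 (adjusted p = 0.0126, adjusted p = 0.786 with an estimated correlation). The muscle isoform genes Cox6a2 (2.67 ± 0.58) and Cox8b (2.16 ± 0.49) rose the most. Against a median of this size, libraries stood apart: GFP+ MPC replicate 2 had a level of -0.31, with 20 of 25 members below both others, and GFP+ myoblast replicate 3 a level of 0.21, with 23 above both. The median was 0.39 without the former and 0.40 without the latter. Glycolysis had 4 of 18 tested members higher and 2 lower (3 and 2 adjusted over the list alone) (median 0.29, adjusted p = 0.81), with a fall of Eno3 (-2.98 ± 0.22) and a rise of Pfkp (1.45 ± 0.18). Cholesterol biosynthesis had 7 of 22 tested members higher and 3 lower (median 0.24, adjusted p = 0.585). Basement membrane and collagen genes had 12 of 22 tested members higher and 1 lower (12 and 2 adjusted over the list alone), with a median of 0.99 (adjusted p = 0.0126, adjusted p = 0.786 with an estimated correlation). Col15a1 was at 1510 ± 242 CPM in GFP+ MPC against 1.06 ± 0.905 in GFP+ myoblasts, Lama4 changed by 6.95 ± 1.34, elastin (Eln) was 438-fold (95% counting interval 121 to 3620) higher, and Col5a2 fell (-2.02 ± 0.44). Oxidative phosphorylation did not pass without GFP+ MPC replicate 3 (adjusted p = 0.0691), nor did basement membrane and collagen genes without GFP+ myoblast replicate 3 (adjusted p = 0.0551). Without GFP+ MPC replicate 2, Cox6a2 was at 1.85 and Lama4 at 6.08. Lama4 was at 7.85 without GFP+ myoblast replicate 2.

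Embryonic and fetal muscle progenitor genes went both ways, with 5 of 21 tested members higher and 6 lower. Their median was -0.01 and their test pointed down, whereas their mean was 0.56 (adjusted p = 0.688). The delta-like gene Dlk1 rose by 7.83 ± 0.69 and Msc was at least 1320-fold higher (at least 507-fold without GFP+ MPC replicate 2), while Hmga2, a chromatin gene of fetal tissues, fell (-5.95 ± 0.50). Pluripotency genes had 0 of 5 tested members higher and 3 lower (median -2.20, adjusted p = 0.0621), and Klf2 (-5.77 ± 0.36), Klf4 (-2.20 ± 0.41) and Esrrb (-2.84 ± 0.72) were the members that fell. Lin28a, another tested member, had 1 count in GFP+ myoblasts and 0 in GFP+ MPC. The result covers these 5 members alone. Interferon-stimulated genes had 4 of 15 tested members higher and 2 lower (3 and 2 adjusted over the list alone) (adjusted p = 0.977), with a median of -0.06 and a mean of -0.24 against a test that pointed up. Genes of sorting and dissociation stress had 4 of 15 tested members higher and 1 lower (median 0.21, adjusted p = 0.783), with rises of Socs3 (3.05 ± 0.61) and Fos (2.90 ± 0.37), at 2.37 and 2.22 without GFP+ MPC replicate 1. That library stood apart over this list: in GFP+ MPC against bulk MPC, the list median was -0.11, and -0.76 without it. Pluripotency genes passed without GFP+ myoblast replicate 1 (adjusted p = 0.0349) or GFP+ MPC replicate 2 (adjusted p = 0.0314), and Esrrb was at -2.05 without GFP+ myoblast replicate 2 and -4.03 without GFP+ MPC replicate 2.

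No list of markers of another cell type passed, except Schwann cell markers without GFP+ MPC replicate 1 (adjusted p = 0.0437). Schwann cell markers had 4 of 6 tested members higher and 1 lower, and their median of 2.95 became 1.90 with genes at 0 counts set to their bound (adjusted p = 0.0652). Ngfr, a neurotrophin receptor gene, changed by 6.68 ± 0.60, Erbb3 by 3.38 ± 0.26 and the myelin gene Mbp by -5.27 ± 0.65 (-6.31 without that library). Pericyte and smooth muscle markers had 6 of 11 tested members higher and 2 lower (median 1.61, adjusted p = 0.269), among them Pdgfrb (4.57 ± 0.97, and 5.57 without GFP+ myoblast replicate 1) and Abcc9 (2.80 ± 0.28). Endothelial markers had 3 of 6 tested members higher and 0 lower, and their median of 1.27 was 0.96 with the bound (adjusted p = 0.393). Adipocyte markers had 2 of 4 tested members higher and 2 lower, a median of -0.21, a mean of 0.34 and a test that pointed up (adjusted p = 0.977); lipoprotein lipase (Lpl) rose by 4.66 ± 0.28. For fibroblast and fibro-adipogenic progenitor markers, 2 of 11 tested members higher and 2 lower (2 and 1 adjusted over the list alone) gave a median of 0.54 (-0.35 without GFP+ MPC replicate 3) and a mean of 0.27, while the test pointed down (adjusted p = 0.81). Macrophage and leukocyte markers had 1 of 5 tested members higher and 1 lower, a median of 0.19, a mean of -0.34 and a test that pointed down (adjusted p = 0.81). Tenocyte markers had 2 of 6 tested members higher and 1 lower, and their median (0.02) and mean (0.85) lay above 0 while the test pointed down (adjusted p = 0.81).

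In all, 7556 genes differed between GFP+ MPC and GFP+ myoblasts, 4032 higher and 3524 lower, of which 1869 and 2101 changed at least 2-fold. With only these groups in the fit, 5218 genes passed, 2410 higher and 2808 lower. Among the largest rises were the collagen gene Col6a6, at least 3610-fold higher against 0 counts in GFP+ myoblasts, the protease gene Adamts15, 15100-fold (95% counting interval 2700 to 595000) higher, and Prrt3, at least 568-fold higher (at least 353-fold without GFP+ MPC replicate 2). Among the largest falls were Dynap (at least 5440-fold lower) and P-selectin (Selp, at least 1270-fold lower and at least 883-fold without GFP+ myoblast replicate 3), both at 0 counts in GFP+ MPC, and Srpx2, 4740-fold (95% counting interval 1310 to 39100) lower. Without the library that held their few counts in the lower group, Adamts15 was at least 3360-fold higher (without GFP+ myoblast replicate 2) and Srpx2 at least 2030-fold lower (without GFP+ MPC replicate 3). Culture medium, serum and passage number also differed between these groups.

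**Figure D1:**
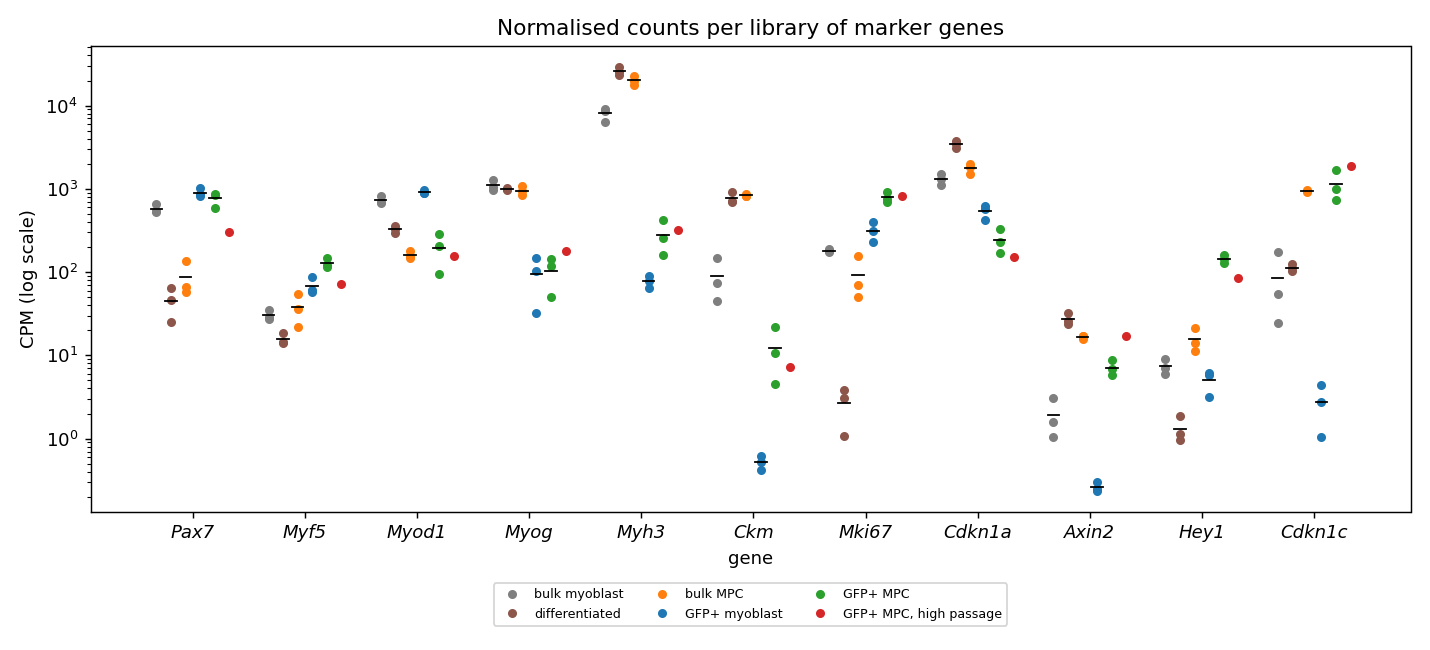
CPM on a log axis of 11 genes in each of the 16 libraries, by group; points are libraries and bars are group means. Pax7 was at 766 ± 148 CPM in GFP+ MPC and 902 ± 92.2 CPM in GFP+ myoblasts, while Hey1 was at 144 ± 14.6 and 5.01 ± 1.62 CPM.

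Unsorted MPC cultures had less Pax7 and Myod1 RNA and more Myh3 and Ckm RNA than unsorted myoblasts. Pax7 fell by 2.73 ± 0.35, to 87 ± 43.8 from 579 ± 69.8 CPM, and Myod1 fell by 2.17 ± 0.28. Myh3 rose to 20100 ± 2610 from 8090 ± 1490 CPM (1.31 ± 0.29), Ckm by 3.24 ± 0.48 and Axin2 by 3.11 ± 0.31. This comparison set the whole small-molecule culture against the myoblasts of passage 3. The MPC cultures came from myoblasts of passage 2 to 3 and then grew for 5 to 6 passages in their medium. Passage therefore could not be separated from the medium. Mki67 was lower (-0.97 ± 0.38, adjusted p = 0.0415), a call that ended in a fit of only these groups (adjusted p = 0.0691) and without bulk myoblast replicate 1, 2 or 3 or bulk MPC replicate 1 or 3 (adjusted p = 0.0697 to 0.15). It was at -1.60 without bulk MPC replicate 2. Cdkn1a did not pass (0.44 ± 0.22, adjusted p = 0.107; 0.0397 with only these groups), nor did Myog (-0.21 ± 0.42).

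Sarcomere genes had 29 of 34 tested members higher and 1 lower (30 and 1 adjusted over the list alone), with a median of 1.40 (adjusted p = 1.34e-07, adjusted p = 0.792 with an estimated correlation). Bulk myoblast replicate 2 had a level of -0.60 and lay below both others in 34 of 34 members, as did bulk MPC replicate 2 in 29 (level -0.32). The median was 1.26 without the former and 1.49 without the latter. The fast myosin gene Myh4 rose by 6.26 ± 0.81 and Myh8 by 3.92 ± 0.45, while the slow myosin gene Myh7 fell (-2.05 ± 0.32). Without bulk myoblast replicate 3, Myh4 was at 6.91. Oxidative phosphorylation had 25 of 25 tested members higher and 0 lower (median 1.17; adjusted p = 5.27e-12, adjusted p = 0.542 with an estimated correlation), with Cyc1 at 1.44 ± 0.13; bulk MPC replicate 2 lay below both others in 23 of 25 (level -0.20). Glycolysis had 14 of 18 tested members higher and 0 lower (median 1.39; adjusted p = 4.56e-07, adjusted p = 0.542 with an estimated correlation), among them Pfkp (3.53 ± 0.19) and hexokinase 2 (Hk2, 2.42 ± 0.35), and bulk myoblast replicate 2 lay below both others in 14 of 18 (level -0.23). Cell cycle genes had 0 of 28 tested members higher and 27 lower (median -1.40; adjusted p = 1.21e-07, adjusted p = 0.792 with an estimated correlation), among them Rrm2 (-3.13 ± 0.33) and Cdc20 (-2.04 ± 0.28). Bulk MPC replicate 2 lay above replicates 1 and 3 in 28 of 28 members, and without it the median was -1.91. Replicate 1 lay below both others in 26 of 28. TGF-beta targets had 0 of 21 tested members higher and 15 lower (median -2.17; adjusted p = 3.49e-05, adjusted p = 0.542 with an estimated correlation), among them Ltbp2 (-4.42 ± 0.65) and Ccn2 (-4.12 ± 0.43). The median was -3.07 without bulk MPC replicate 2.

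No list of markers of another cell type passed in this comparison. Fibroblast and fibro-adipogenic progenitor markers had 2 of 11 tested members higher and 4 lower (2 and 3 adjusted over the list alone) (median -0.73, adjusted p = 0.411). Tenocyte markers had 1 of 6 tested members higher and 2 lower (median -0.42, adjusted p = 0.524). Without bulk MPC replicate 2 these medians were -1.64 and -2.40. Pericyte and smooth muscle markers had 5 of 11 tested members higher and 2 lower (median 0.90, adjusted p = 0.411). Endothelial markers had 3 of 6 tested members higher and 0 lower (4 and 0 adjusted over the list alone) (median 0.98, adjusted p = 0.431). Schwann cell markers had 2 of 6 tested members higher and 1 lower (median 0.59, adjusted p = 0.576).

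Stem cell markers went both ways, with 8 of 28 tested members higher and 8 lower, a median of 0.10, a mean of -0.12 and a test that pointed up: Cdkn1c rose (3.49 ± 0.60) and Vcam1 fell (-3.33 ± 0.53). Notch genes had 3 of 15 tested members higher and 6 lower (median -0.45), with Hey1 at 1.08 ± 0.27 and Lfng at -2.31 ± 0.56. Of the Wnt targets, 5 of 16 tested members higher and 6 lower (5 and 8 adjusted over the list alone) gave a median of -1.08, with Lef1 at -2.34 ± 0.40. In bulk MPC replicate 2, 12 of the 15 Notch genes lay above replicates 1 and 3. None of these 3 lists passed, with adjusted p values of 0.882, 0.576 and 0.859. Without bulk MPC replicate 2, Vcam1 was at -4.51 and Lfng at -3.24, and without bulk myoblast replicate 3 Cdkn1c was at 4.57. Mitochondrial transcripts made up 8.37% to 9.85% of counts in bulk MPC and 2.11% to 6.34% in the other groups. Of 9088 genes past the threshold, 4408 were higher and 4680 lower, 2379 and 2589 of them by at least 2-fold. With DESeq2 size factors 4637 were higher and 4503 lower, and with its Wald test 4724 and 4601. Parvalbumin (Pvalb, 8.64 ± 0.69) and Atp1b4 (8.90 ± 0.58, and 9.66 without bulk myoblast replicate 3) were among the largest rises. Dynap, 6750-fold (95% counting interval 1210 to 267000) lower, and the chemokine gene Cxcl12, 5520-fold (95% counting interval 991 to 218000) lower, were among the largest falls. Without bulk MPC replicate 1, which held their only count there, Dynap was at least 1420-fold and Cxcl12 at least 1170-fold lower.

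Cultures in differentiation medium had less Pax7 RNA, at 45.5 ± 19.8 CPM, and more Myh3 and Ckm RNA than bulk myoblasts. Mki67 fell by 6.11 ± 0.49, to 2.65 ± 1.41 from 181 ± 9.79 CPM, Cdkn1a rose by 1.39 ± 0.23, Myh3 by 1.68 ± 0.29 and Ckm by 3.12 ± 0.47. Myod1 (-1.15 ± 0.27) and Myf5 (-0.95 ± 0.27) fell, and Myog was at 1000 ± 29.4 and 1100 ± 166 CPM (-0.14 ± 0.42, adjusted p = 0.794). Axin2 rose (3.82 ± 0.31) as well. The comparison addressed terminal differentiation, and the groups also differed in passage, 4 to 5 against 3.

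All cell cycle members were lower (0 of 28 tested members higher and 28 lower; median -4.51; adjusted p = 4.88e-14, adjusted p = 0.367 with an estimated correlation), among them Bub1 (-5.92 ± 0.49) and Top2a (-5.87 ± 0.49), and differentiated myoblast replicate 1 lay below both others in 23 (level -0.43). Sarcomere genes had 33 of 34 tested members higher and 0 lower (median 1.68; adjusted p = 4.64e-12, adjusted p = 0.367 with an estimated correlation), with Myh2 at 3.95 ± 0.64 (3.03 without differentiated myoblast replicate 3) and Myh4 at 3.56 ± 0.71 (4.20 without bulk myoblast replicate 3). Bulk myoblast replicate 2 lay below both others in 34 of these 34 (level -0.60), and the median was 1.51 without it. Oxidative phosphorylation had 24 of 25 tested members higher and 0 lower (median 0.75; adjusted p = 1.03e-09, adjusted p = 0.367 with an estimated correlation), with Cox7a1 at 3.35 ± 0.41, and differentiated myoblast replicate 3 lay below both others in 24 of 25 (level -0.19). Cholesterol biosynthesis had 16 of 22 tested members higher and 0 lower (18 and 0 adjusted over the list alone) (median 1.17; adjusted p = 4e-08, adjusted p = 0.367 with an estimated correlation), led by Dhcr7 (2.59 ± 0.23) and Fdps (2.10 ± 0.20). Notch genes had 0 of 15 tested members higher and 11 lower (median -1.22; adjusted p = 0.00425, adjusted p = 0.367 with an estimated correlation), including Notch3 (-3.58 ± 0.43) and Hey1 (-2.49 ± 0.33). Notch3 is also on the list of pericyte and smooth muscle markers. TGF-beta targets had 1 of 21 tested members higher and 11 lower (median -1.41; adjusted p = 0.0383, adjusted p = 0.682 with an estimated correlation), with Col3a1 at -3.48 ± 0.68 and, against the majority, Pmepa1 at 1.73 ± 0.22. The TGF-beta list did not pass without bulk myoblast replicate 3 (adjusted p = 0.0616) or differentiated myoblast replicate 1 (adjusted p = 0.0717) or 2 (adjusted p = 0.0512). Differentiated myoblast replicate 1 had a level of -0.82 over this list, and replicate 3 a level of 0.62. Fibroblast and fibro-adipogenic progenitor markers had 0 of 11 tested members higher and 6 lower (1 and 7 adjusted over the list alone) and a median of -2.35, or -1.58 without bulk myoblast replicate 3 (adjusted p = 0.234). Pericyte and smooth muscle markers had 2 of 11 tested members higher and 4 lower (3 and 4 adjusted over the list alone) (median -0.15, or 0 with genes at 0 counts at their bound, adjusted p = 0.937), and no list of markers of another cell type passed. Stem cell markers had 6 of 28 tested members higher and 17 lower and a median of -1.22 but did not pass (adjusted p = 0.0748), although they did without bulk myoblast replicate 2 (adjusted p = 0.0309). The chemokine receptor gene Cxcr4 fell (-4.17 ± 0.40). The fusion gene Mymk rose (1.38 ± 0.27). There were 8417 genes past the threshold, 3976 higher and 4441 lower, with 1756 and 2472 changed at least 2-fold. With DESeq2 size factors 4232 were higher and 4186 lower, and with its Wald test 4363 and 4287.

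Bulk MPC and differentiated myoblasts did not differ past the threshold in Myh3, Ckm or Myog but did in Mki67. Medium and passage both differed between these groups. Myh3 was at 20100 ± 2610 and 25900 ± 2910 CPM (-0.37 ± 0.28, adjusted p = 0.314), Ckm at 836 ± 31.6 and 770 ± 120 CPM and Myog at 953 ± 114 and 1000 ± 29.4 CPM. Mki67 was at 91.9 ± 56.9 CPM in bulk MPC against 2.65 ± 1.41 CPM (5.13 ± 0.48, and 4.51 without bulk MPC replicate 2), Cdkn1a was lower (-0.95 ± 0.23) and Myf5 higher (1.27 ± 0.27). Pax7 was higher at 87 ± 43.8 against 45.5 ± 19.8 CPM (0.94 ± 0.34, adjusted p = 0.0372), a call that ended in a fit of only these groups (adjusted p = 0.114) and without differentiated myoblast replicate 1 or 3 or bulk MPC replicate 2 (adjusted p = 0.0859 to 0.252).

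Cell cycle genes had 27 of 28 tested members higher and 0 lower (28 and 0 adjusted over the list alone) (median 3.00; adjusted p = 7.22e-10, adjusted p = 0.494 with an estimated correlation), with Aurkb at 4.88 ± 0.54 and Bub1 at 4.66 ± 0.49. In bulk MPC replicates 1 to 3, Bub1 was at 7.53, 25.3 and 11.1 CPM and Aurkb at 8.88, 28.8 and 13.9 CPM. Replicate 2 was the highest for 28 of 28 members. Without it the list median was 2.53 (adjusted p = 7.67e-11), Aurkb was at 4.28 and Bub1 at 4.00. Without differentiated myoblast replicate 2 Aurkb was at 5.73. Stem cell markers had 14 of 28 tested members higher and 1 lower (14 and 3 adjusted over the list alone) (median 0.78, or 0.70 with genes at 0 counts at their bound; adjusted p = 0.014, adjusted p = 0.416 with an estimated correlation), among them Hey1 (3.57 ± 0.33) and Cdkn1c (3.07 ± 0.59). Notch genes had 8 of 15 tested members higher and 0 lower (median 0.84; adjusted p = 0.014, adjusted p = 0.494 with an estimated correlation), with Notch3 at 3.04 ± 0.42 and Heyl at 2.89 ± 0.67. Without bulk MPC replicate 2, in which 12 of the 15 lay above replicates 1 and 3, the Notch list did not pass (adjusted p = 0.0515) and Notch3 was at 2.43. Replicate 1 had a level of -0.64 over the Notch genes. Hey1, Heyl and Notch3 are on both the Notch and the stem cell lists. Pericyte and smooth muscle markers, a list that also holds Notch3, had 5 of 11 tested members higher and 1 lower (median 1.51, adjusted p = 0.265). Schwann cell markers had 3 of 6 tested members higher and 1 lower (median 1.58, adjusted p = 0.439). Glycolysis had 13 of 18 tested members higher and 0 lower (median 0.85; adjusted p = 1.13e-07, adjusted p = 0.416 with an estimated correlation), led by Pfkp (4.54 ± 0.20) and the glucose transporter gene Slc2a1 (2.37 ± 0.28). Oxidative phosphorylation had 15 of 25 tested members higher and 0 lower (median 0.36; adjusted p = 0.000701, adjusted p = 0.69 with an estimated correlation), including Ndufb8 (0.65 ± 0.11). Over the latter list, bulk MPC replicate 2 had a level of -0.20, with 23 of 25 members below both others, and differentiated myoblast replicate 3 a level of -0.19, with 24 below both. Its median was 0.45 without the former and 0.28 without the latter. Differentiated myoblast replicate 3 also lay below both others in 15 of 18 glycolysis genes (level -0.24).

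Cholesterol biosynthesis was lower in bulk MPC (0 of 22 tested members higher and 19 lower (0 and 21 adjusted over the list alone); median -1.50; adjusted p = 2.92e-13, adjusted p = 0.416 with an estimated correlation), with Insig1 at -2.74 ± 0.23 and Cyp51 at -2.18 ± 0.14. TGF-beta targets had 1 of 21 tested members higher and 8 lower (median -1.03; adjusted p = 0.00683, adjusted p = 0.494 with an estimated correlation), with Pmepa1 at -2.60 ± 0.23 and Acta2 at -2.38 ± 0.38. Over this list, bulk MPC replicates 2 and 3 had levels of 0.56 and -0.63, and differentiated myoblast replicates 1 and 3 levels of -0.82 and 0.62. The list median was -1.85 without bulk MPC replicate 2. Fibroblast and fibro-adipogenic progenitor markers had 3 of 11 tested members higher and 0 lower (median 0.03, or 0.63 without differentiated myoblast replicate 2, adjusted p = 0.916), and no list of markers of another cell type passed. Bulk MPC replicate 2 had a level of 2.52 over the fibroblast and fibro-adipogenic progenitor markers, and without it their median was -0.56. Targets of cAMP and CREB had 10 of 20 tested members higher and 2 lower (11 and 2 adjusted over the list alone) (median 0.76, adjusted p = 0.0656). They passed with a block for library number (adjusted p = 0.0403) and without bulk MPC replicate 2 (adjusted p = 0.0472). Within the sarcomere list (2 of 34 tested members higher and 8 lower, median -0.13, adjusted p = 0.227), Myh4 was higher (2.71 ± 0.69) and the slow or oxidative fibre genes Myh7 (-3.18 ± 0.33) and Mb (-1.86 ± 0.35) were lower. The count was 6812 genes, 3793 higher and 3019 lower, with 1874 and 1516 at least 2-fold. With only these groups in the fit, 7112 genes passed, 3532 higher and 3580 lower. Among the largest rises were Nnat, at least 326-fold higher against 0 counts (at least 171-fold without bulk MPC replicate 1), and Gpc3 (9.01 ± 0.60, and 9.63 without differentiated myoblast replicate 1). Wwc1, 904-fold (95% counting interval 250 to 7470) lower (at least 387-fold without bulk MPC replicate 2, which held its 2 counts), and the adenylyl cyclase gene Adcy8 (-8.88 ± 0.67, and -8.28 without bulk MPC replicate 2) were among the largest falls.

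Sorting the MPC culture for GFP gave cells with more Pax7 and Mki67 RNA and less Myh3, Ckm and Myog RNA than the culture as a whole. Pax7 was 3.14 ± 0.36 higher, at 766 ± 148 against 87 ± 43.8 CPM, Mki67 3.12 ± 0.41 (3.74 without bulk MPC replicate 2) and Myf5 1.76 ± 0.27 higher. Myh3 fell by 6.16 ± 0.35, to 281 ± 135 from 20100 ± 2610 CPM, and Ckm (-6.09 ± 0.55, and -6.79 without GFP+ MPC replicate 2), Myog (-3.19 ± 0.46) and Cdkn1a (-2.86 ± 0.24) fell too. Myod1 did not pass, at 195 ± 95.2 against 162 ± 16.3 CPM (0.27 ± 0.27, adjusted p = 0.393), although it did without GFP+ MPC replicate 1 (adjusted p = 0.00294). The comparison addressed what the reporter enriches within this culture, and RNA of sorted cells was prepared with another kit.

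Every sarcomere member was lower in sorted cells (0 of 34 tested members higher and 34 lower; median -5.38; adjusted p = 4.94e-17, adjusted p = 0.339 with an estimated correlation), with Myh4 at -7.25 ± 0.85 and Myh1 at -6.21 ± 0.46. Fusion and synapse genes had 0 of 12 tested members higher and 10 lower (median -2.48; adjusted p = 0.000115, adjusted p = 0.339 with an estimated correlation), with Mymk at -4.47 ± 0.31 and Chrng at -4.69 ± 0.28. Myogenic regulatory factors had 1 of 7 tested members higher and 5 lower (median -2.26; adjusted p = 0.0431, adjusted p = 0.339 with an estimated correlation), with Myf6 (-5.65 ± 0.45) and Mef2c (-5.20 ± 0.31) lower and Myf5 higher. The list did not pass without GFP+ MPC replicate 1 (adjusted p = 0.0757). Glycolysis had 0 of 18 tested members higher and 16 lower (median -1.45; adjusted p = 4.61e-06, adjusted p = 0.339 with an estimated correlation), including Pgam2 (-5.41 ± 0.50, and -6.17 without GFP+ MPC replicate 2). Oxidative phosphorylation had 0 of 25 tested members higher and 25 lower (median -0.90; adjusted p = 6.84e-08, adjusted p = 0.339 with an estimated correlation). GFP+ MPC replicate 2 had a level of 1.05 over the sarcomere list and -0.31 over oxidative phosphorylation. Over fusion and synapse genes, GFP+ MPC replicate 1 had a level of -0.59 and bulk MPC replicate 2 a level of -0.31. Over glycolysis, GFP+ MPC replicates 1 and 3 had levels of 0.48 and -0.45. Bulk MPC replicate 2 lay below both others in 29 of 34 sarcomere members and 23 of 25 of oxidative phosphorylation.

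Cell cycle genes were higher throughout (28 of 28 tested members higher and 0 lower; median 3.04; adjusted p = 7.73e-13, adjusted p = 0.339 with an estimated correlation), with Ccna2 at 3.48 ± 0.34 and Foxm1 at 3.38 ± 0.39. The median was 3.53 without bulk MPC replicate 2. Notch genes had 12 of 15 tested members higher and 2 lower (median 2.83; adjusted p = 0.00598, adjusted p = 0.339 with an estimated correlation), with the fringe gene Lfng at 4.67 ± 0.59 and Dtx4 at 3.36 ± 0.40, against Jag2 at -2.37 ± 0.19. Lfng was at 5.60 without bulk MPC replicate 2 and 4.05 without GFP+ MPC replicate 2. Basement membrane and collagen genes had 13 of 22 tested members higher and 1 lower (median 1.53; adjusted p = 0.00533, adjusted p = 0.688 with an estimated correlation), with Col4a1 at 2.59 ± 0.47 and Lamb1 at 2.63 ± 0.57. Bulk MPC replicate 2 lay above replicates 1 and 3 in 19 of these 22, and replicate 1 below both others in 20. Without replicate 2 the median was 2.35, Col4a1 was at 3.58 and Lamb1 at 4.02. Stem cell markers had 15 of 28 tested members higher and 5 lower and a median of 1.65 without passing (adjusted p = 0.0661, but 0.0495 without bulk MPC replicate 1). Cxcr4 (3.48 ± 0.36) and Heyl (3.25 ± 0.65) were higher, and Des, the muscle intermediate filament gene, was lower (-3.23 ± 0.21).

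No list of markers of another cell type passed. Fibroblast and fibro-adipogenic progenitor markers had 1 of 11 tested members higher and 2 lower (0 and 2 adjusted over the list alone) (adjusted p = 0.974) and tenocyte markers 3 of 6 tested members higher and 1 lower (adjusted p = 0.934). Pericyte and smooth muscle markers had 3 of 11 tested members higher and 4 lower (adjusted p = 0.934). The medians of these 3 lists were -0.07, 0.37 and 0.68, and without bulk MPC replicate 2 they were 2.13, 2.16 and 1.30. That of pericyte and smooth muscle markers was -0.42 without GFP+ MPC replicate 1. Of 10350 genes past the threshold, 5118 were higher and 5232 lower, with 2933 and 3496 changed at least 2-fold. With only these groups in the fit, 4405 were higher and 4331 lower.

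The effect of this sort ran opposite to that of differentiation. Across 15533 genes, the log2 fold changes of GFP+ MPC against bulk MPC and of differentiated against bulk myoblasts, which share no library, had a Pearson r of -0.543. Computed from libraries of the same number, r was -0.563, -0.465 and -0.565 (SD 0.057). Genes are not independent replicates, so no p is given, and the RNA kit differed along with the sort. Of the genes higher after sorting, 3092 were lower in differentiation, 2.11 times the 1463 of independent calls, and 2887 lower after sorting were higher in differentiation, 2.16 times the 1339 of independent calls. Only 208 were higher in both, against 1310 of independent calls, and 314 lower in both, against 1496. Without the filter on low counts r was -0.346.

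**Figure D2:**
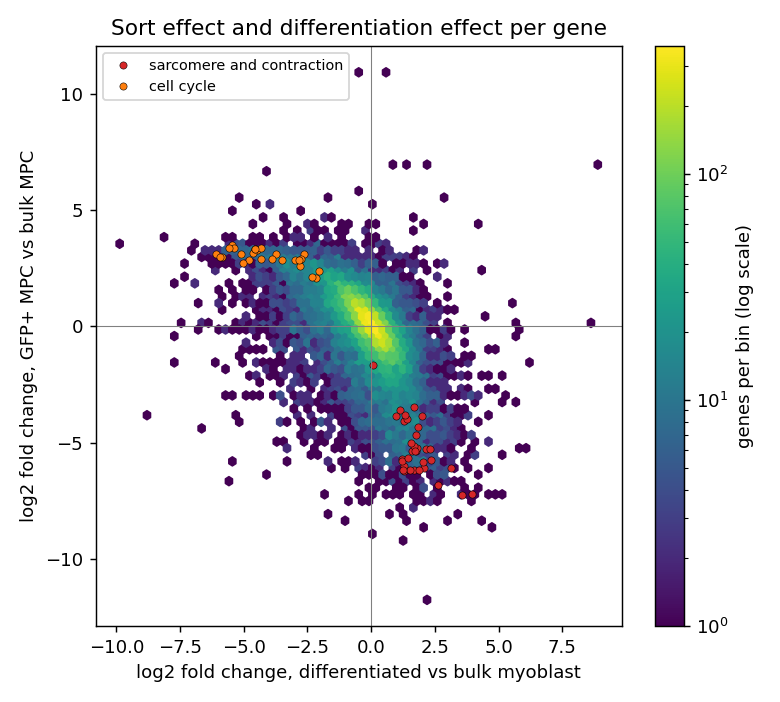
Log2 fold change of differentiated against bulk myoblasts (x axis) and of GFP+ MPC against bulk MPC (y axis) for 15533 genes, shaded by gene number, with sarcomere and cell cycle genes marked. Sarcomere genes had a median of 1.68 on the x axis and -5.38 on the y axis, and cell cycle genes -4.51 and 3.04.

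In ordinary myoblast culture, sorted cells had less Myh3 and Myog RNA, without a Pax7 change past the threshold. Pax7 was at 902 ± 92.2 CPM in GFP+ myoblasts and 579 ± 69.8 CPM in bulk myoblasts (0.64 ± 0.33, adjusted p = 0.159); with only these groups in the fit it passed (adjusted p = 0.00942). Myh3 fell by 6.71 ± 0.36, to 77.2 ± 13 from 8090 ± 1490 CPM, Myog (-3.54 ± 0.47) and Cdkn1a (-1.28 ± 0.23) fell, and Myf5 rose by 1.17 ± 0.27. Myod1 (0.33 ± 0.27) did not pass. The groups also differed in RNA kit and in passage, 5 to 6 against 3.

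All sarcomere members were lower (0 of 34 tested members higher and 34 lower; median -6.14; adjusted p = 5.81e-35, adjusted p = 0.165 with an estimated correlation), with Ckm at -7.38 ± 0.65 and Tcap at -7.08 ± 0.34. Bulk myoblast replicate 2 lay below both others in 34 of 34 (level -0.60). Cell cycle genes had 25 of 28 tested members higher and 0 lower (27 and 0 adjusted over the list alone) (median 1.06; adjusted p = 1.68e-12, adjusted p = 0.489 with an estimated correlation), among them the replication licensing genes Mcm2 (1.41 ± 0.30) and Mcm5 (1.37 ± 0.27). GFP+ myoblast replicate 3 had a level of 0.63 over this list, with 26 of 28 members above both, and replicate 2 lay below both others in 27. The list median was 0.82 without replicate 3 and 1.16 without replicate 2. Fusion and synapse genes had 0 of 12 tested members higher and 8 lower (0 and 9 adjusted over the list alone) (median -1.03; adjusted p = 2.73e-05, adjusted p = 0.419 with an estimated correlation), with Mymx at -3.99 ± 0.52, and GFP+ myoblast replicate 3 had a level of -0.32. Myogenic regulatory factors had 1 of 7 tested members higher and 5 lower (median -1.55; adjusted p = 0.00757, adjusted p = 0.419 with an estimated correlation), with Mef2c at -5.84 ± 0.33. Pericyte and smooth muscle markers had 0 of 11 tested members higher and 6 lower (median -1.18; adjusted p = 0.0169, adjusted p = 0.489 with an estimated correlation), with Abcc9 at -5.77 ± 0.30 and Lmod1 at -3.77 ± 0.40, and GFP+ myoblast replicate 3 had a level of -0.67 and bulk myoblast replicate 3 of 0.36. The muscle gene Des and Notch3 are on this list and on that of stem cell markers, so it cannot tell pericytes from muscle cells. Schwann cell markers had 0 of 6 tested members higher and 2 lower (median -1.59, or -0.68 with genes at 0 counts at their bound, adjusted p = 0.489), and fibroblast and fibro-adipogenic progenitor markers had 0 of 11 tested members higher and 1 lower (median -0.42, adjusted p = 0.534). The Notch list did not pass (0 of 15 tested members higher and 0 lower, median -0.06, adjusted p = 0.911).

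The number of genes was 4667, 1966 higher and 2701 lower, with 285 and 1728 at least 2-fold. Without bulk myoblast replicate 3 it was 2719, of which 828 were higher, and the number higher was 1106 without bulk myoblast replicate 1 and 1089 without GFP+ myoblast replicate 3. By the naming rule, the largest falls included the muscle protease gene Capn3 (-8.53 ± 0.52, and -9.57 without GFP+ myoblast replicate 1) and Xirp2 (-8.26 ± 0.50). The largest rises included Cxcl12 (2.01 ± 0.40, and 1.42 without GFP+ myoblast replicate 3) and the replication gene Cdc6 (1.75 ± 0.39).

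**Figure D3:**
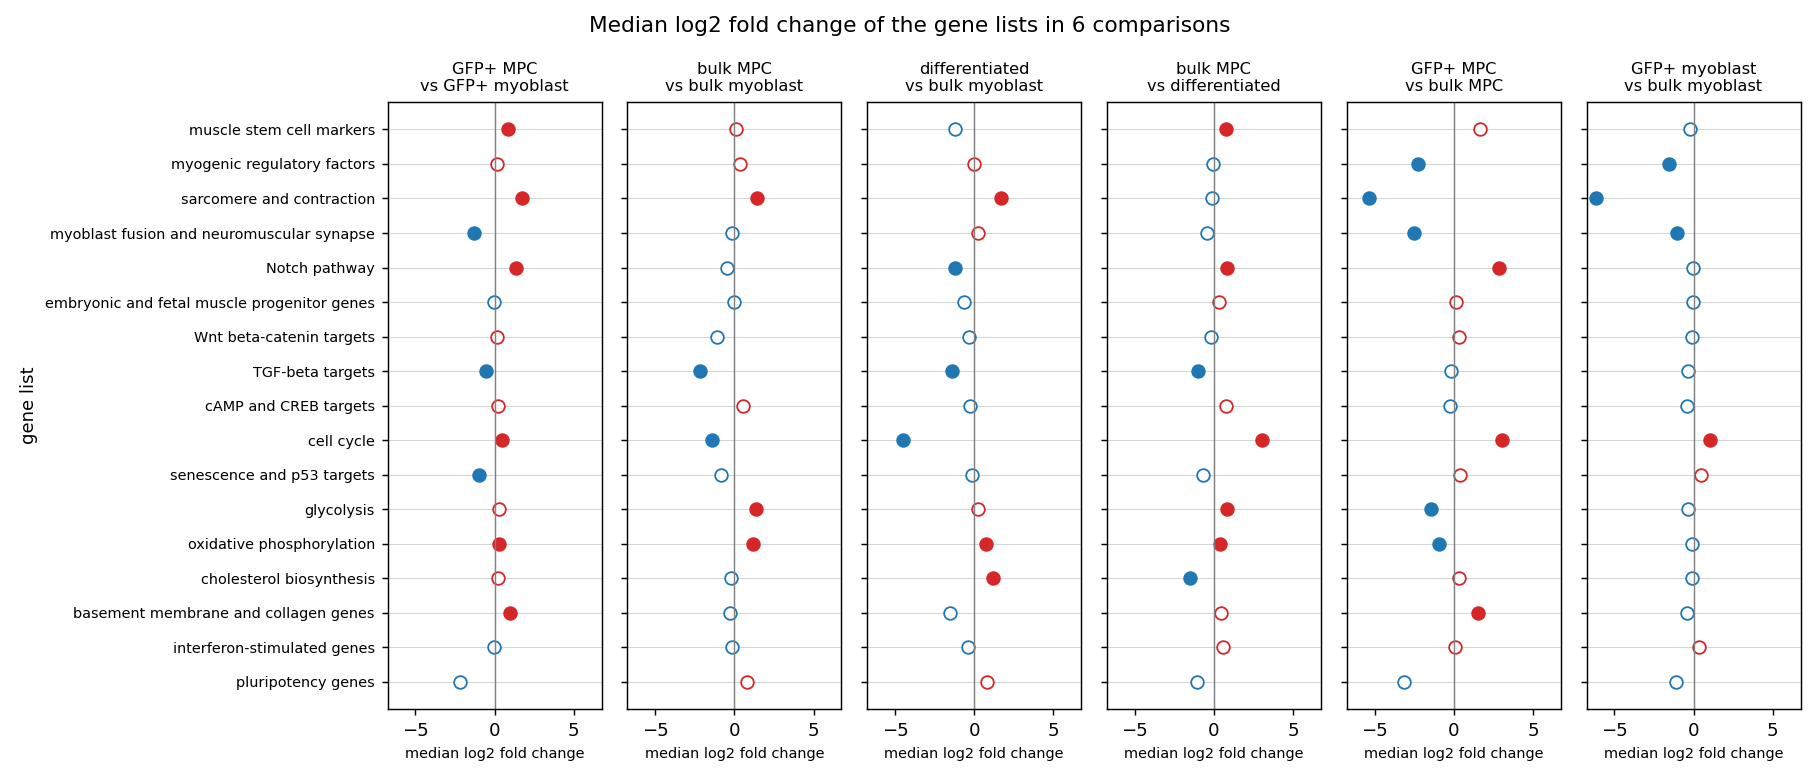
Median log2 fold change of the tested members of each pathway or treatment list (y axis, lists; x axis, log2) in a panel for each of 6 comparisons; filled marks passed an adjusted p of 0.05 with a preset correlation, red marks lie above 0 and blue marks below 0. The cell cycle median was -4.51 in differentiated against bulk myoblasts and 3.04 in GFP+ MPC against bulk MPC.

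The high-passage library came from myoblasts sorted as GFP-negative at passage 8, grown for 2 passages in MPC medium and sorted as GFP+, from a 39-week-old female, against 16-week-old males for the other libraries. It had no replicate, and its sex, age, parental line and passage could not be separated from the culture. Pax7 was at 303 CPM, Myod1 at 155, Hey1 at 85.5, Cdkn1c at 1900 and Dlk1 at 1550 CPM. Of 3970 genes that differed at least 2-fold between GFP+ MPC and GFP+ myoblasts, 3423 had a level nearer the GFP+ MPC mean, 86.2%. With each library of those groups left out of the fit and the means and then placed in the same way, the share was 87.7%, 89.8% and 84.6% for GFP+ MPC and 4.22%, 3.94% and 16.9% for GFP+ myoblasts. Xist, the RNA of the inactive X chromosome, was at 2840 CPM in this library and at most 0.861 CPM in the others.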

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

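Only the counts of extreme genes in the other libraries and the list medians without single libraries were chosen after the result was seen. The effect of the sort differed between the MPC and myoblast cultures at 5755 genes in a test of the difference itself. Splits of the samples could not decide on chance for this count. In all, 9 of 100 splits, the real one included, gave at least as many genes, and the highest count of a split other than the real one was 10126. Each of these 9 kept sorted and unsorted MPC apart, and the highest count among the 91 splits that did not was 70. A split that keeps them apart and mixes the myoblasts carries the sort effect of MPC into the difference, and every such split drawn reached the count, so a share under 0.05 was out of reach. Splits that call so many genes point to a structure of the samples, here the sort within the MPC culture. The RNA kit differed between sorted and unsorted cells in both cultures. Passage differed between sorted and unsorted myoblasts, 5 to 6 against 3, but not between sorted and unsorted MPC. Passage therefore could not be separated from the difference of sort effects.

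The difference was 2.50 ± 0.47 for Pax7 (adjusted p = 0.00131), 2.31 ± 0.54 for Mki67 (adjusted p = 0.00472), 1.61 ± 0.48 for Axin2 (adjusted p = 0.0181, and 0.0628 with limma-voom) and -1.58 ± 0.32 for Cdkn1a (adjusted p = 0.00188). Pax7 did not differ past the threshold between the sorted groups, whereas it was lower in unsorted MPC than in unsorted myoblasts. Both sorts selected cells by the reporter of Pax7, so like Pax7 levels in the sorted groups could follow from the selection. The Pax7 difference is thus no independent result of the sort. Values of genes with 0 to 3 counts in a group are fitted ones that depend on the fit's prior, and are no bounds. Among the largest positive differences were those of Col6a6 (9.20, with GFP+ myoblasts at 0 counts, adjusted p = 0.0499), Moxd1 (7.62, with 3 counts there), Capn6 (7.62 ± 0.67), Adamts15 (7.51, with 1 count there) and Col15a1 (6.999). Among the largest negative ones were those of Elf3 (-7.93, with 1 to 6 counts in each of the 3 groups other than bulk MPC), B4galnt3 (-7.19 ± 0.63), Cd24a (-6.27 ± 0.69), Cgref1 (-5.55 ± 0.32) and Cacna1i (-5.53 ± 0.96). The call of Col6a6 ended with DESeq2 size factors (adjusted p = 0.0506), limma-voom (0.123), only these groups (0.0792) and with any of 9 single libraries left out (0.055 to 0.215). Without bulk myoblast replicate 3, Adamts15 was at 5.47 (adjusted p = 0.0745), and without GFP+ myoblast replicate 3 Elf3 was at -5.40 (adjusted p = 0.961). Their values at the other end were 9.23 for Adamts15 (without GFP+ myoblast replicate 2) and -9.76 for Elf3 (without GFP+ MPC replicate 2). Col6a6 lay between 7.78 (without bulk myoblast replicate 3) and 11.39 (without bulk MPC replicate 2), and Moxd1 was at 8.31 without GFP+ myoblast replicate 1. With single libraries left out, Cacna1i lay between -7.34 (without GFP+ MPC replicate 1) and -4.77 (without GFP+ myoblast replicate 1), and Col15a1 between 5.96 (without bulk myoblast replicate 3) and 7.90 (without GFP+ myoblast replicate 1).

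List medians of this difference were 1.67 for muscle stem cell markers (adjusted p = 0.00518, adjusted p = 0.299 with an estimated correlation), 2.88 for Notch (adjusted p = 0.0013, adjusted p = 0.299 with an estimated correlation), 2.06 for cell cycle (adjusted p = 3.48e-12, adjusted p = 0.401 with an estimated correlation) and 2.28 for basement membrane and collagen genes (adjusted p = 0.000289, adjusted p = 0.501 with an estimated correlation). They were -1.18 for fusion and synapse genes (adjusted p = 0.0013, adjusted p = 0.406 with an estimated correlation), -1.29 for glycolysis (adjusted p = 3.54e-08, adjusted p = 0.299 with an estimated correlation), -0.78 for oxidative phosphorylation (adjusted p = 4.35e-09, adjusted p = 0.401 with an estimated correlation) and -2.11 for pluripotency genes (adjusted p = 0.0442, adjusted p = 0.299 with an estimated correlation). The stem cell and Notch lists share Hey1, Heyl and Notch3. Without bulk MPC replicate 2, which stood apart from replicates 1 and 3, the medians were 2.27 for stem cell markers, 3.49 for Notch, 2.63 for cell cycle and 3.07 for basement membrane and collagen genes, and the difference of Mki67 was 2.94. The pluripotency list had only 5 tested members. It did not pass with DESeq2 size factors (adjusted p = 0.0562), nor without GFP+ myoblast replicate 2, GFP+ MPC replicate 2 or 3 or bulk MPC replicate 2 (adjusted p = 0.0571 to 0.0828), and its median was -3.13 without GFP+ MPC replicate 2. No list of markers of another cell type passed. Fibroblast and fibro-adipogenic progenitor markers had a median of 1.36, or 2.96 without bulk MPC replicate 2 (adjusted p = 0.653), and pericyte and smooth muscle markers 1.43, or 2.17 (adjusted p = 0.653).

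For the other comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each. Its count and the highest of the others were 7556 and 3 for GFP+ MPC against GFP+ myoblasts, 9088 and 0 for bulk MPC against bulk myoblasts, and 8417 and 0 for differentiated against bulk myoblasts. They were 6812 and 1 for bulk MPC against differentiated, 10350 and 2 for GFP+ MPC against bulk MPC, and 4667 and 0 for GFP+ myoblasts against bulk myoblasts.

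In the high-passage library, which no comparison used, 1646 genes lay above and 1541 below all 15 other libraries. An even share among 16 libraries would be 971 genes on each side. In the other libraries, each with 2 replicates in its group, 265 to 1693 genes lay above and 214 to 1787 below all others. Among protein-coding genes above all others, the largest gaps on the log scale were those of Cpa1 (379 CPM), Prph (20.7 CPM), Crispld2 (30.5 CPM), Wscd1 (134 CPM) and Vipr1 (38.3 CPM). With no replicate of this library, no test was made.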

How the results depend on the processing

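The alternative fits were chosen before the data were seen, and the list medians, list levels and bounds with single libraries left out were added after. For GFP+ myoblasts against bulk myoblasts, 4667 genes became 2719 without bulk myoblast replicate 3; the cause was not tested. Of 175 list tests, 48 passed, 0 with an estimated correlation and 91 with fry, which tests against no change rather than against the other genes. The r of sort and differentiation effects was -0.543, -0.346 without a filter on low counts, where more genes with few counts enter, and -0.645 over genes called in differentiation alone. Other alternatives kept the total of each gene count within 1.5 times its value, but not the number higher in GFP+ MPC against GFP+ myoblasts, 4032, which was 2410 with only the groups compared. For GFP+ myoblasts against bulk myoblasts, 1966 higher became 828 and 1106 without bulk myoblast replicates 3 and 1, and 1089 without GFP+ myoblast replicate 3. The direction with more genes also turned with DESeq2 size factors or its Wald test in bulk MPC and in differentiated against bulk myoblasts. With only the groups compared, it turned in GFP+ MPC against GFP+ myoblasts, bulk MPC against differentiated and GFP+ MPC against bulk MPC. With each library left out in turn, the counts were 6353 to 7706 (GFP+ MPC against GFP+ myoblasts), 7926 to 8825 (bulk MPC against bulk myoblasts), 6940 to 7912 (differentiated against bulk myoblasts), 5472 to 6084 (bulk MPC against differentiated), 9604 to 10259 (GFP+ MPC against bulk MPC), 2719 to 4110 (GFP+ myoblasts against bulk myoblasts) and 4836 to 6006 (difference of sort effects). List tests were 46 to 51, r was -0.568 to -0.51, and the high-passage share was 84.4% to 87%. A block for library number gave 7319, 8986, 8222, 6578, 10233, 4404 and 5559 genes in that order. It gave 49 list tests, with cAMP and CREB targets in bulk MPC against differentiated gained (adjusted p = 0.0403, against 0.0656). Replicates 1 to 3 of each group carry the numbers 74, 75 and 76, which could mark shared animals or lines, but the labels give no animal. The numbers were not used as pairs in the main fit: same-numbered libraries had a median r of 0.023 (-0.166 to 0.209) after group means were removed, over 0.1 in 8 of 30 pairs. They did serve in the rule for naming genes and in the r of sort and differentiation effects by number. In favour of pairs, 10 of 15 libraries correlated best with one of their own number, and bulk myoblasts and bulk MPC of the same number had r of 0.134, 0.131 and 0.163. Libraries of these 2 groups with different numbers had r of -0.141 to -0.019. With length-scaled counts, 2 calls of bulk MPC against bulk myoblasts and 3 of GFP+ MPC against bulk MPC changed sign. Of 3023 values of named genes under alternatives, 2993 kept direction and side of the threshold, 27 lost the threshold and 3 gained it. At 19.3 to 29.1 M counts per library, depth limits genes of few counts, where folds are bounds (0 counts in a group) or ratios with a wide counting interval (1 to 3 counts).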

Other observations

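Tests on read number, a wrong label, carried-over RNA and fusion genes were chosen only after the results were seen. Genes of this part other than Dlk1 and Cdkn1c were also chosen after their values were seen. Imprinted genes, expressed from a single parental copy, differed between sorted cells of the MPC and myoblast cultures. Igf2, a fetal growth factor gene, was at 10300 ± 804 CPM in GFP+ MPC and 1730 ± 1270 CPM in GFP+ myoblasts (2.57 ± 0.46, and 3.20 without GFP+ myoblast replicate 1), and Dlk1 (7.83 ± 0.69) and Cdkn1c (8.64 ± 0.77) rose. H19, which shares its control region with Igf2, did not pass (0.02 ± 0.19, adjusted p = 0.948), nor did Peg3 (0.19 ± 0.17, adjusted p = 0.377). Igf2r (2.31 ± 0.14), Grb10 (2.77 ± 0.39), Airn (2.50 ± 0.30) and Meg3 (3.83 ± 0.86, and 3.16 without GFP+ MPC replicate 2) were higher, and belong to the set tested below.

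The explanation tested was a general rise of imprinted genes in GFP+ MPC. It was tested over 26 imprinted genes, which exclude Igf2, Dlk1, Cdkn1c, H19 and Peg3 but include Igf2r, Grb10, Airn and Meg3. Of the 26, 15 (those 4 among them) were higher and 6 lower, with a median of 0.99 and a camera p of 0.0119, which became 0.163 with an estimated correlation. The values such a rise needs were there at the preset correlation alone. Imprinted genes can share a control region, as Igf2 and H19 do. The 26 may therefore not be independent of each other or of the genes left out. For this reason the test cannot tell a general rise from that of a few groups of genes with shared control. In bulk MPC against bulk myoblasts, 11 of the 26 were higher and 6 lower, with a median of 0.035. Of the 15 higher in GFP+ MPC, Meg3, Mirg, Rian and Rtl1 were lower there than in bulk MPC (-3.96, -4.71, -3.40 and -3.72). In that comparison 8 of the 26 were higher and 8 lower. Whether medium, passage, selection of cells, RNA carried over from bulk MPC or differentiating cells could underlie the rise in GFP+ MPC was not tested.

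In the high-passage library, Cdkn2a and Cdkn2b, neighbouring genes of cell cycle inhibitors lost in many immortal lines, had 0 counts. They were not alone in this. Gria3, Col4a5 and Sdk1 also had 0 counts, against at least 3.85, 3 and 2.36 CPM in the other 15 libraries, as did the sex-linked genes Ddx3y and Uty. Why Gria3, Col4a5 and Sdk1 were at 0 counts was not tested. In the other 15 libraries Cdkn2a was at 13.5 to 73.3 CPM, at least 105-fold higher at its lowest, and Cdkn2b at 3.42 to 31.6 CPM, at least 26.5-fold higher. Too few reads would have needed under 3 expected counts, and the smaller expectation was 79.6. A library of a male sample under a wrong label would have had Xist within the range of the others, and it was 3290 times the highest of them. A deletion reaching the nearest tested protein-coding genes on both sides was argued against by 2 of 2 neighbours within the range of the others (Mtap at 130 CPM, others 32.6 to 169; Tusc1 at 1.46 CPM, others 0.234 to 2.54). A smaller deletion, of Cdkn2a and Cdkn2b alone, would leave both neighbours expressed and was not tested. It stays open, as do the sex, age, parental line and passage of this library, also untested.

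Sarcomere genes were higher in GFP+ MPC than in GFP+ myoblasts, and RNA carried over from the unsorted MPC culture could raise them. The share allowed for each GFP+ MPC library was the median of its 5 lowest ratios to bulk MPC among 1999 genes outside the lists. These genes had at least 100 CPM in bulk MPC. The share was 0.837%, 0.794% and 0.241% in GFP+ MPC replicates 1 to 3. Of 26 higher genes, 15 exceeded the GFP+ myoblast level plus this share in all 3 libraries, and 11 did not, for which carry-over cannot be told apart from expression. This share assumes carried-over RNA with the make-up of the whole unsorted culture. Carry-over from only some cells of that culture was not tested and stays open for the 15 as well. The test covered the sarcomere list alone, and not Myf6, Mef2c, Cox6a2, Cox8b or imprinted genes. A larger share of fusing, differentiating cells also stays open. Fusion and synapse genes were higher in 0 of 12, but the median share of the bulk MPC level in the higher sarcomere genes, 2.17%, would double only 1 of these 12, so a small share of such cells would not show.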
